A study of Mus musculus with 415 samples.

How the data were processed

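Chromatin accessibility was measured by single-cell ATAC-seq, in which the Tn5 transposase cuts open chromatin and leaves sequencing adapters there, so that sequenced fragments mark accessible DNA. The cells were mouse embryonic stem cells of the R1 line that had been aggregated into embryoid bodies in hanging drops for 48 hours and then kept in retinoic acid for 4 days, at a concentration that the labels give as 0.5 mM. Per the labels' protocols, single cells were captured and tagmented on a Fluidigm C1 microfluidic chip, and the libraries were amplified by 13 further PCR cycles. Each of the 415 samples is 1 cell, and all of them carry the same treatment and time point. The labels name no separate cultures, chips or sequencing runs. The series therefore holds 1 sample in the statistical sense, cells are not replicates of it, and no p-value or standard error was computed from cells. Exact (Clopper-Pearson) 95% intervals are given for shares of cells. They cover the counting of cells only.

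The deposited table gives a whole number for each of 23180 genomic regions in each of the 415 cells. The values are deposited signal, not counts of reads. Of the values above 0, 37.6% equal 148, 5.98% equal 296 and 4.44% equal 74, and 51.1% are whole multiples of 74, which is the pattern of aligned bases summed over reads of 74 bases that come in pairs, with smaller values where a read overlaps a region's edge. The label fields name no counting tool, and this reading of the unit rests on the values. The submitters' processing notes name MACS2, a peak caller, and the mouse genome build mm9, without saying how the regions were chosen. The aligner, the treatment of PCR duplicates and the rule that selected regions are not given in the sources used here. Every region held signal in at least 31 cells, or 7.47% of them, so rarer regions were not analysed here. The regions do not overlap each other, lie on the 19 autosomes and chromosome X, and span 150 to 11051 bp with a median of 762 bp. The regions are shared by all cells. No pair of cells held identical values. Coordinates are printed as the table gives them, on mm9.

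The table names no genes. The gene table at hand is on the later build GRCm38, and coordinates were not carried between builds, so regions are named by position and cell clusters by number. The accessibility of lists of marker genes, the naming of clusters by marker genes and the count of transcription factor motifs had been planned, need a gene annotation or a genome sequence on mm9, and were not run.

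A region was called open in a cell when its value was above 0. Signal was converted to fragments by dividing by 148, the bases of 1 read pair. Counts had been assumed when the comparisons were designed. The minimum of 1000 counts per cell that had been set before the data were examined was read as 1000 fragments. It removed 1 cell from the clustering and from the comparison of fragments per chromosome. Depth varied widely, from 756 to 12267 open regions and from 791 to 25069 fragments per cell, so a closed region in a shallow cell is mostly a region that was not sampled. An expected probability of being open was fitted for each region and cell as 1 − exp(−region rate × cell rate), with rates that match the observed number of open cells per region and open regions per cell. Residuals from it, divided by their expected standard deviation, served for the comparisons that correct for depth, and data drawn from it served as background without any difference between cells.

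Cells were clustered from open and closed values weighted by term frequency and inverse document frequency (scaled by 10000, log-transformed), reduced by singular value decomposition to components 2 to 10, the first being left out as a guard against depth, whose relation to it was not measured, and grouped into 3 clusters by k-means with 50 starts. The number 3 was fixed before the data were examined, as the number of subpopulations that the study is known to have used. It may therefore not be independent of these cells. The study's own method factorises chromatin and expression data together; the expression data were not used here. To keep the regions that are read apart from those that define the clusters, cells were clustered once on the 10 odd-numbered and once on the 9 even-numbered autosomes, the clusters of 1 set were read on the other set, and agreement was measured by the adjusted Rand index, which is 1 for identical groupings and about 0 for unrelated ones. A held-out region was counted as higher or lower in a cluster when its share of open cells differed at least 2-fold from that in all other cells and the exact intervals did not overlap. The same count was taken over 20 shuffles of the cluster membership within 5 depth classes. Both of the following corrections for depth are given beside the observed shares. Either each cell was thinned at random to 1500 open regions, which left out 32 shallower cells, or shares were divided by their expected values. The latter correction and the depth of 1500 were chosen after seeing the data, as were the conversion to fragments and the distance classes above 5 Mb. No doublet caller was run.

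The regions named in the text follow a rule fixed before the data were examined, except that the treatment of low counts in ratios was settled after values had been seen, which changed the order of regions in cluster 3. Counts of 1 to 3 cells entered as they were, and a count of 0 was replaced by a floor of 3. The rule takes the 5 autosomal regions open in most cells, the 5 with the largest variance over the expected one, and for each cluster the 5 held-out regions with the largest ratio of shares. The alternatives were other depth limits, a stricter definition of open, other numbers of clusters, non-negative matrix factorisation, other region filters, thinning and fragments in place of open calls. Regions of very high signal (a median of at least 2.5 fragments in open cells) were left out as an alternative chosen after seeing the data. On simulated data with the real depths and region frequencies, the clustering recovered 3 planted groups with an adjusted Rand index of 1. With known membership, the rule for held-out regions found 80% of 100 regions raised 3-fold in 1 group and 95% of 100 regions raised 5-fold. It also called 27 unchanged autosomal regions higher in that group. With random membership and no difference, the rule made 184 calls, higher or lower, over 3 groups. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.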

Results

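The series measured chromatin accessibility in single cells of 1 differentiation experiment, R1 mouse embryonic stem cells after embryoid body formation and 4 days in retinoic acid, a vitamin A derivative that drives early embryonic cells towards differentiated fates. Its stated purpose was a method that groups single cells by accessibility and expression jointly. Each sample was 1 cell. There was 1 treatment and no untreated group, so the design holds no comparison between conditions. The comparisons that remain are between regions, between chromosomes and between groups of cells within the culture.

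A median cell had 3928 of the 23180 regions open, with quartiles of 2546.5 and 5690.5 and a range of 756 to 12267. This was 16.9% of the regions, and the median signal was 4530 fragments per cell. The matrix was therefore sparse, with 18.4% of its values above 0.

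**Figure D1:**
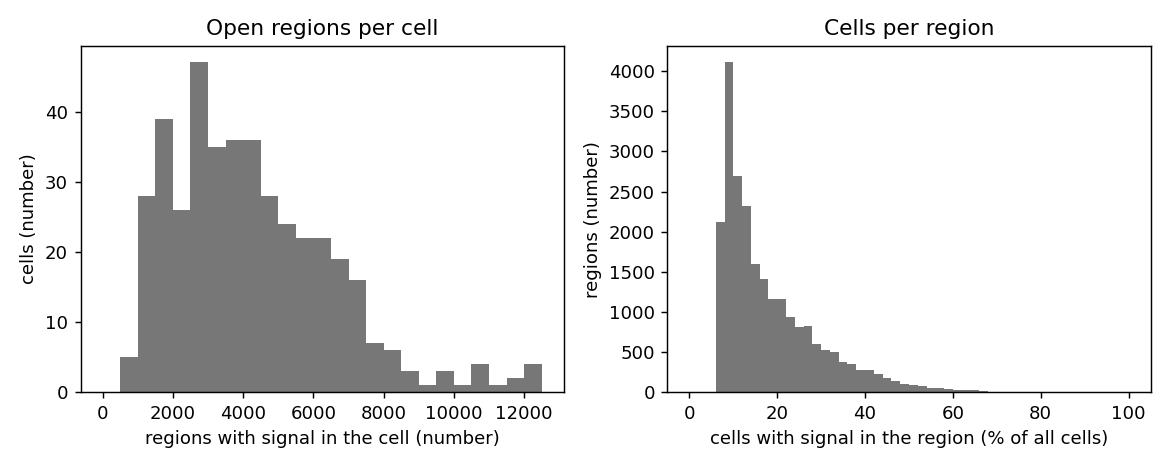
Histograms of the number of open regions per cell (left, in cells) and of the percentage of cells in which each of 23180 regions was open (right, in regions, bins of 2 percentage points). The median region was open in 14.5% of the cells and none in fewer than 7.47%, the lower limit of the deposited table.

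Most regions were open in a minority of cells, and a small group of wide regions was open in most. The median region was open in 14.5% of cells (quartiles 9.88% and 23.6%). Regions open in at least 50% of the cells numbered 451, or 1.95% of all, and had a median width of 1137 bp. The 6231 regions open in under 10% of cells, 26.9% of all, had a median width of 541 bp. Regions on chromosome X were open in 15.8% of cells on average, and those on autosomes in 18.4%. Among open values outside the regions of very high signal, 24.8% on chromosome X and 29.3% over all chromosomes exceeded 1 fragment. These shares depend on depth and on the definition of open. In the cells at or above the median depth 2046 regions reached 50%, and with more than 1 fragment required 20 regions did.

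The 5 autosomal regions open in most cells were all regions of very high signal. The region on chromosome 1 from 24618733 to 24620285 was open in every cell (100%, interval 99.1% to 100%) with a median of 96.6 fragments per cell, and it alone held 1.96% of all signal. The region on chromosome 2 from 98506406 to 98507478 was also open in every cell, with a median of 49.7 fragments and 1.88% of all signal. On chromosome 17, the region from 39979995 to 39983587 was open in 97.8% of cells (95.923% to 99.004%) at 13.2 fragments. A second region on chromosome 2, from 98502396 to 98503114, was open in 95.2% (92.66% to 97.03%) at 5.86 fragments. The fifth, on chromosome 2 from 22444044 to 22445731, was open in 94.5% (91.8% to 96.5%) at 3.64 fragments. In all, 14 regions had a median of at least 2.5 fragments in open cells and held 6.07% of all signal, from 1.22% to 39.5% of a single cell's fragments. Whether they lie in repeated sequence was not checked, since no genome sequence on this build was used here.

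Outside those 14 regions, the most widely open were single regions of 808 to 1880 bp. The region on chromosome 15 from 102235765 to 102237135 was open in 330 cells (79.5%, interval 75.3% to 83.3%). It was followed by chromosome 17 from 57170900 to 57171708 with 78.1% (73.78% to 81.96%) and chromosome 16 from 38088351 to 38089865 with 75.7% (71.2% to 79.7%). The regions on chromosome 9 from 56923169 to 56925049 and on chromosome 14 from 22318811 to 22320599 were open in 75.2% (70.7% to 79.3%) and 73.7% (69.2% to 77.9%) of cells. Each of these 5 had a median of 2 fragments in open cells. The intervals of all 5 overlap, so their order is not established.

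Divided into 3 groups, a number taken beforehand from the study, the cells were grouped largely alike on separate sets of chromosomes. Cluster 1 held 46.1% of the clustered cells (interval 41.3% to 51.1%), cluster 2 held 27.3% (23.1% to 31.9%) and cluster 3 held 26.6% (22.4% to 31.1%). The adjusted Rand index between clusters made on the odd-numbered and on the even-numbered autosomes was 0.787, and 92.8% of the cells had the same cluster in both. In 100 data sets drawn without clusters the index lay between 0.180 and 0.272, above 0 because depth alone separates some cells alike on both sets. Over 50 random divisions of the autosomes it was between 0.734 and 0.910. After every cell had been thinned to 1500 open regions, the index was 0.758, against at most 0.00805 in 100 simulated data sets drawn at that equal depth.

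**Figure D2:**
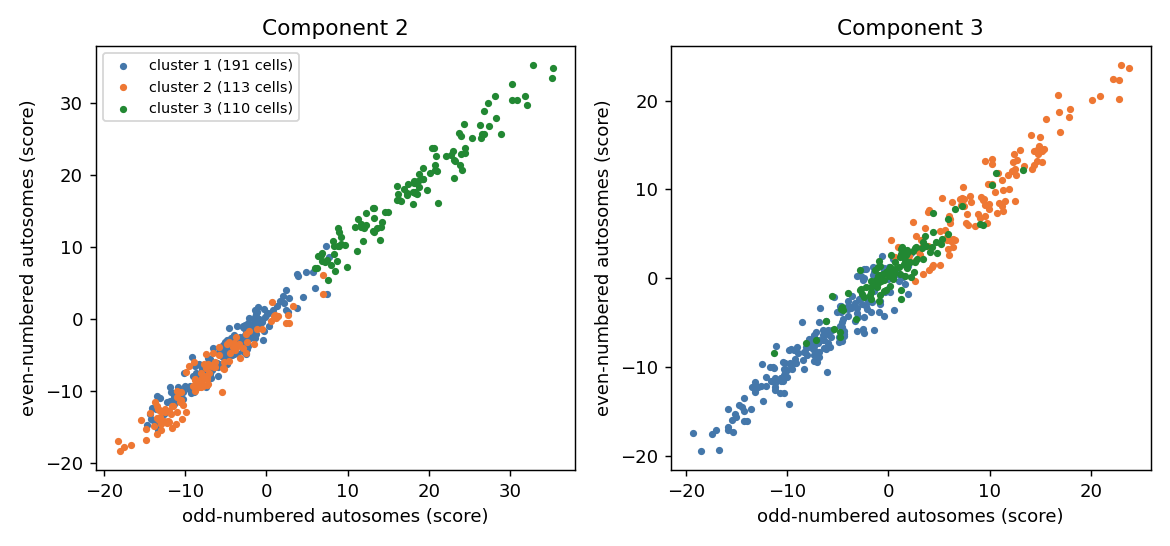
Scores of the clustered cells on components 2 and 3 of the decomposition, computed on the odd-numbered autosomes (horizontal) and on the even-numbered autosomes (vertical); each point is 1 cell, coloured by its cluster on all chromosomes. Cluster 3 (26.6% of cells) lies at the high end of component 2 and cluster 2 (27.3%) at the high end of component 3, and neighbouring clusters touch without a gap.

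Cluster 3 was the most sharply separated of the 3 groups. When 2 clusters were requested in place of 3, all 110 of its cells formed 1 part together with 2 cells of cluster 1 and 1 cell of cluster 2, and the other part joined the rest of clusters 1 and 2. The index for 2 clusters was 0.960 where data without clusters gave 0.602 to 0.822. The boundary between clusters 1 and 2 was less fixed, and depth differed across it. The median cell had 3628 open regions in cluster 1, 4778 in cluster 2 and 3700 in cluster 3, and 27 of the 32 cells too shallow for thinning belonged to cluster 1. Scores of neighbouring clusters touched without a gap. This does not decide between ranges along these axes and closed classes, because sparse sampling of cells can also blur distinct groups. Scores of distinct groups at the same depths were not examined. Shares of the clusters also differed along the title numbers of the cells, whose meaning the labels do not give. With the cells divided by title number into 4 consecutive sets of about equal size, cluster 3 made up 38.5% (interval 29.1% to 48.5%) of the lowest numbers, then 38.8% (29.4% to 48.9%), 14.4% (8.30% to 22.7%) and 14.6% (8.39% to 22.9%) of the highest. Cluster 1 made up 34.6%, 38.8%, 56.7% and 54.4% of these sets. Cluster 3 was not spread evenly within the sets of lower numbers. Its cells were more frequent on both sides of the boundary between the lowest set and the next than farther from it. Clustered within each set alone, odd and even autosomes gave an index of 0.632, 0.865, 0.934 and 0.671, where data without clusters gave at most 0.313. Clusters made within these sets matched those of all cells with an index of 0.581, 0.941, 0.868 and 0.292, and 100 random sets of as many cells gave 0.399 to 1. Within every set, 1 cluster overlapped cluster 3 by at least 0.778 of the cells in either. The division between clusters 1 and 2 was recovered less well within the lowest numbers, where the best overlaps with them were 0.540 and 0.413, and within the highest, where they were 0.448 and 0.492.

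Regions outside the chromosomes used for clustering differed in accessibility between the clusters, by a rule that combines a 2-fold difference with the counting error of cells and is not a test across replicates. Of 22681 autosomal regions, 494 were higher and 2778 lower in cluster 1 than in the other cells, 3079 were higher and 310 lower in cluster 2, and 1984 were higher and 3174 lower in cluster 3. Shuffled membership gave at most 3, 846 and 25 higher regions in clusters 1, 2 and 3, and at most 425, 4 and 82 lower ones. The balance between higher and lower changed with the correction for depth. Higher regions made up 15.1% of those that differed in cluster 1, 90.9% in cluster 2 and 38.5% in cluster 3 on observed shares. With shares scaled by expected depth these percentages were 39.7%, 62.6% and 44.3%, and with thinned cells 46.7%, 78.7% and 74.8%, so in cluster 3 the corrections gave opposite majorities. Scaled by depth, 1096 regions were higher and 1662 lower in cluster 1, 1706 higher and 1018 lower in cluster 2, and 2108 higher and 2652 lower in cluster 3, where shuffled membership gave at most 57 in any of these 6 counts. After thinning, 1.36%, 2.63% and 5.38% of the regions were higher in clusters 1, 2 and 3, and 1.56%, 0.714% and 1.82% were lower. Shuffled membership gave at most 44 regions in any of these 6 classes.

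The regions that were higher in a cluster were narrower and less often open over the culture than the median autosomal region. On the depth-scaled counts, their median width was 612.5 bp in cluster 1, 623.5 bp in cluster 2 and 605 bp in cluster 3, against 760 bp over all autosomal regions. They were open in a median of 10.8%, 10.8% and 9.88% of all cells, against 14.5%. The rule itself keeps out the most widely open regions, because a share can hardly be 2-fold higher where most of the other cells are open too. Width goes with that share over the whole table, where regions open in under 10% of cells had a median width of 541 bp. The narrower width may therefore follow from the rule alone. Widths were not compared with those of regions matched for the share of open cells, so a difference in width beyond the rule was not tested.

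In cluster 3, the region with the largest ratio lay on chromosome 15 from 84858186 to 84858522. It was open in 30 cells of the cluster (27.03%, interval 19.04% to 36.28%) and in 2 other cells (0.660%, 0.0800% to 2.36%), a ratio of 40.9 with a counting interval of 10.4 to 353.6. The region on chromosome 1 from 31213131 to 31213918 was open in 36.04% of cluster 3 (27.14% to 45.70%) and 0.990% of the other cells (0.205% to 2.87%), and that on chromosome 3 from 103059997 to 103060358 in 35.1% (26.3% to 44.8%) and 1.32% (0.361% to 3.35%). Those on chromosome 11 from 69789822 to 69790019 and on chromosome 18 from 67716422 to 67716768 were open in 25.2% and 31.1% of cluster 3 and in 0.990% and 1.29% of the other cells.

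In cluster 2, the region on chromosome 18 from 16828530 to 16828957 was open in 31 cells of the cluster (28.97%, interval 20.61% to 38.54%) and in 3 other cells (0.977%, 0.202% to 2.83%), a ratio of 29.6 (counting interval 9.25 to 151.6). The others were on chromosome 15 from 88808963 to 88809608 (28.8% against 1.35%), chromosome 2 from 83236928 to 83237566 (27.1% against 1.30%), chromosome 15 from 91930260 to 91930670 (26.3% against 1.69%) and chromosome 18 from 89733829 to 89734203 (25.2% against 1.63%). In cluster 1, ratios were smaller. The region on chromosome 17 from 27538216 to 27538471 was open in 31 cells of the cluster (16.8%, 11.7% to 22.9%) and in 3 other cells (1.31%, 0.271% to 3.78%), a ratio of 12.8 (3.99 to 65.4). It was followed by chromosome 16 from 5523446 to 5523926 (20.1% against 1.90%), chromosome 7 from 108895210 to 108895467 (16.2% against 1.75%), chromosome 1 from 130348829 to 130349056 (15.7% against 1.75%) and chromosome 15 from 94912088 to 94912587 (14.6% against 1.75%). At most 5 cells outside the cluster were open at any of these 15 regions. Scaled by depth the 15 ratios ran from 10.4 to 44.5. These regions were picked for their size among many, so their ratios lean high.

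**Figure D3:**
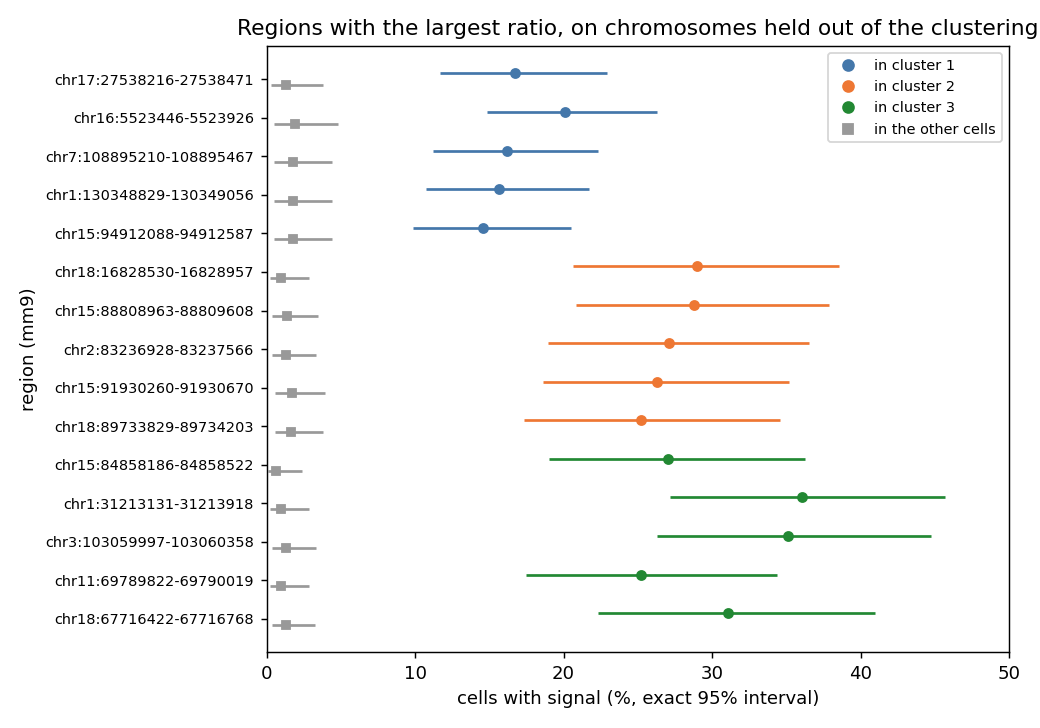
Share of cells with signal (horizontal, percent) at the 5 held-out regions with the largest ratio in each cluster; circles are cells of the cluster, squares all other cells, and bars exact 95% intervals. Shares in the cluster run from 14.6% to 36.04% and those in the other cells stay below 2%.

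Regions near each other on a chromosome tended to be open in the same cells, and the tendency weakened with distance. The mean correlation of depth-corrected values over cells was 0.0444 ± 0.0164 (SD over 20 chromosomes) for 496 pairs under 2 kb apart. It was 0.0348 ± 0.0108 at 2 to 10 kb, 0.0229 ± 0.00533 at 10 to 50 kb, 0.0149 ± 0.00304 at 50 to 200 kb and 0.0101 ± 0.00112 at 200 kb to 1 Mb. At 1 to 5 Mb it was 0.00672 ± 0.000975. Pairs over 50 Mb apart on 1 chromosome still had a mean of 0.00304 ± 0.00107, while pairs on different chromosomes had -0.000228. The fit matches each cell's number of open regions, which holds the mean over all pairs near 0. The value between chromosomes is therefore no separate background, and it does not show that regions on different chromosomes open independently. Data drawn from depth and region frequency alone gave 0.00152 under 2 kb and 3.3e-06 over 50 Mb. Every chromosome was above 0 in every distance class, with 0.00199 as the lowest value over 50 Mb. Pairs are not independent of each other, so no test was made across them.

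**Figure D4:**
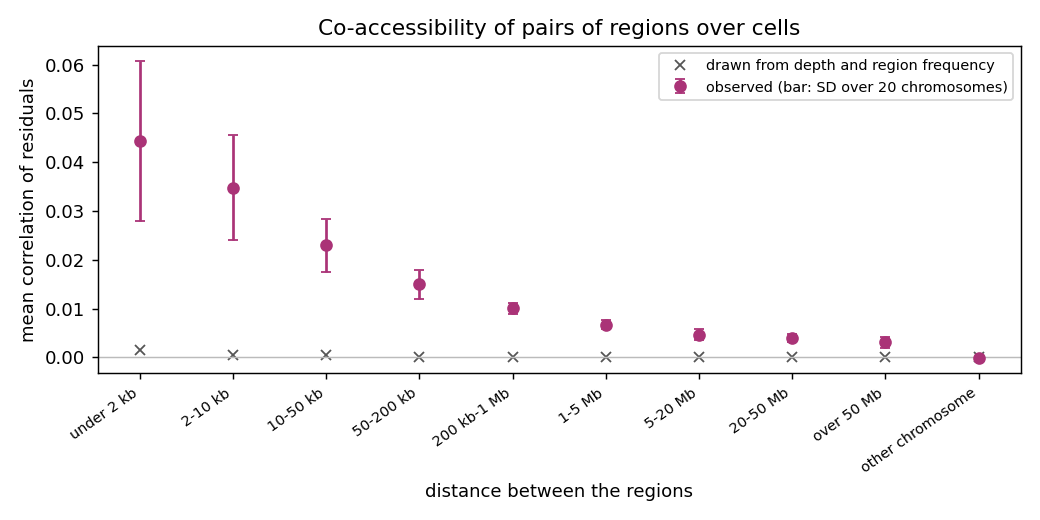
Mean correlation over all cells of depth-corrected open values for pairs of regions, by distance; circles are observed means with bars for the SD over 20 chromosomes, and crosses are values from simulated data. The mean falls from 0.0444 under 2 kb to 0.00304 over 50 Mb and is -0.000228 between chromosomes.

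Single cells also differed in how much of their accessible signal came from each chromosome. The variance over cells of a chromosome's share of fragments was a median of 9.06 times that of multinomial sampling over the 19 autosomes, where 200 simulated data sets gave medians of 0.933 to 1.06. The ratio was highest on chromosomes 2 (44.998), 17 (24.6) and 1 (19.1), which carry the regions of highest signal, and without the 14 such regions these were 10.9, 8.10 and 10.9. The median over autosomes was then 8.60. Counted as open regions on 20 chromosomes, the median ratio was 6.11, from 4.31 on chromosome 14 to 7.88 on chromosome 11, where simulated medians were at most 1.03. On chromosome X the ratio was 4.62, with 499 regions. Where regions of a chromosome open together, this ratio rises with their number, which was 843 on chromosome 14 and 1776 on chromosome 11. It therefore does not rank chromosomes by spread. Open regions over expected ones ran from 0.654 to 1.39 (5th to 95th percentile of cells) on chromosome X and from 0.803 to 1.22 on chromosome 11. Simulated data gave 0.802 to 1.21 and 0.909 to 1.09.

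Among the cells at or above the median depth, 17 of 4160 combinations of cell and chromosome held under 0.6 of the expected open regions and 41 held over 1.4 times that number. The highest of 20 simulated data sets gave 0 and 1. Those combinations lay in 11 and 31 cells. Over all cells, the lowest value was 0.279, for chromosome 14 in 1 cell, and the highest 2.12, for chromosome 16.

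**Figure D5:**
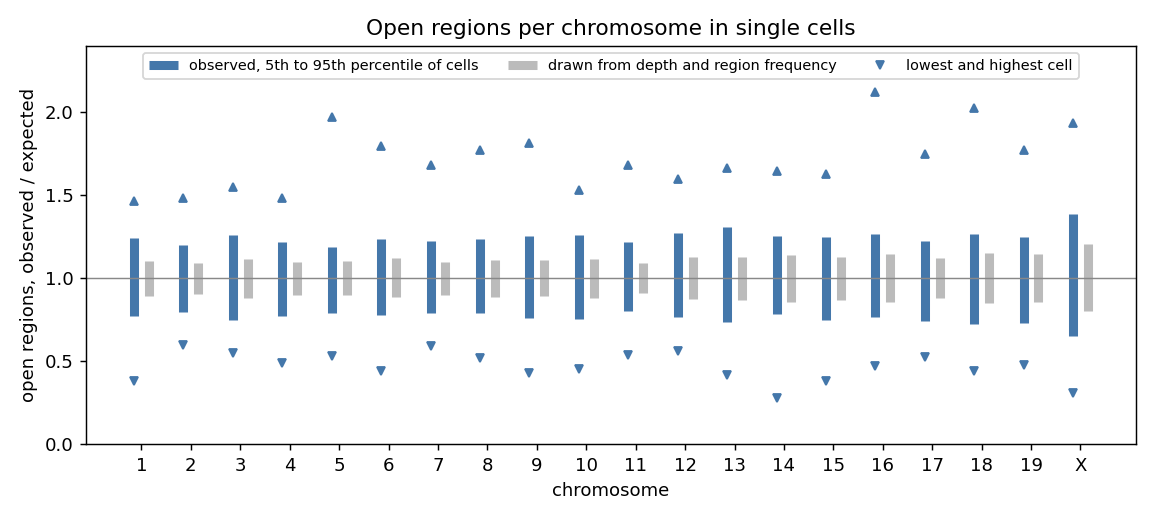
Open regions per chromosome in single cells, as observed over expected from depth and region frequency (vertical); blue bars span the 5th to 95th percentile of all cells, triangles mark the lowest and highest cell, and grey bars show the same percentiles of simulated data. Observed ranges exceed simulated ones on all 20 chromosomes, for example 0.772 to 1.24 against 0.896 to 1.11 on chromosome 1.

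Taken region by region, the variance of an open or closed value is set almost wholly by its mean, so this measure can show little excess spread and says nothing of its absence. In all, 19 regions exceeded the limit that 0.1% of simulated values pass, where 23.2 were expected, and 10 of the 19 were regions of very high signal. The 5 largest ratios were 46.4 on chromosome 17 from 39984380 to 39985695, 34.5 on chromosome 2 from 98502396 to 98503114, 33.1 on chromosome 17 from 39979995 to 39983587, 14.8 on chromosome 6 from 103599085 to 103599283 and 12.8 on chromosome 12 from 3109872 to 3110098. All 5 were among the 14 regions of very high signal.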

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

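Leaving out regions of very high signal, scaling by depth and distances above 5 Mb were chosen after seeing the data. Of the alternatives, those that keep only regions open in at least 2% or 5% of cells, or drop such a filter, change nothing, because every region is open in at least 7.47% of cells. Accessibility of gene lists was not run, so its alternatives were not run either. The regions open in at least 50% of cells numbered 20 when more than 1 fragment was required and 2046 in the deeper cells. The largest cluster held 46.1% of cells, and 72.7%, 30.2% and 29.5% with 2, 4 and 5 clusters, 39.4% with the first component kept, 40.98% in cells with at least 5000 fragments and 39.8% after thinning. In these last 3, membership matched that of the 3 clusters with an adjusted Rand index of 0.367, 0.887 and 0.822, so keeping the first component gave a largely different grouping. With 4 clusters, a part of 25.6% of the cells with a median of 2288.5 open regions drew from all 3 clusters. Agreement of odd and even autosomes moved from 0.787 to 0.960 with 2 clusters, 0.712 with 4 and 0.844 with non-negative matrix factorisation, and stayed above every simulated value for 2 and 3 clusters. With 5 clusters it was 0.768, so agreement does not single out 3 as the number of groups. Held-out calls of a region as higher or lower in a cluster, summed over the 3 clusters, numbered 11819 and, after thinning, 3053. By cluster, thinning left 1.36% of regions higher and 1.56% lower in cluster 1, 2.63% and 0.714% in cluster 2, and 5.38% and 1.82% in cluster 3, and thinning uses fewer open values. Scaling by depth gave 4.83% and 7.33% in cluster 1, and 7.52% and 4.49% in cluster 2. Regions with excess variance numbered 11 in deeper cells and 9 without those of very high signal. With fragments in place of open calls the mean correlation was 0.0750 under 2 kb, 0.0372 at 50 to 200 kb and 0.0253 at 1 to 5 Mb, but pairs on different chromosomes were then at 0.0154, so these values hold a part common to all pairs. In deeper cells it was 0.0194 at 50 to 200 kb and 0.00933 at 1 to 5 Mb, and 0.00812 at 1 to 5 Mb for regions in at least 10% of cells. The median variance ratio of chromosome shares lay between 4.27 (regions open in at most 20% of cells) and 13.7 (cells with at least 5000 fragments), within the SD of 9.08 over chromosomes, which the high ratios of chromosomes 2, 17 and 1 make wide. The causes of these shifts were not tested. Shallow cells limit every statement about a region being closed.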

Other observations

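The tests on sampling, whole chromosomes, the density of regions, doublets, the membership of clusters within sets of title numbers and the overlap of cluster 3 were chosen after the result had been seen. The design names no biological explanation, and of biological causes only gain or loss of whole chromosomes was tested.

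Regions higher in a cluster lay near each other more often than regions drawn at random from the same table. On depth-scaled shares, 46 windows of 100 kb held at least 3 regions higher in cluster 3, where the highest of 100 random draws of as many regions had 24. For cluster 2 there were 24 such windows against at most 14, and for cluster 1 12 against at most 6, so uneven density of all regions of the table along the chromosomes did not account for the grouping. The draws were not matched for width or for the share of open cells. Uneven density of narrow, rarely open regions was therefore not tested. Among the windows with most such regions, that of cluster 3 on chromosome 15 held 5 of 11 regions, between 101834686 and 101859042, with ratios of 6.53 to 10.4. On chromosome 18, 4 of 4 regions between 10903997 and 10948794 had ratios of 4.32 to 9.71, and on chromosome 14, 4 of 4 between 63902240 and 63961458 had ratios of 2.56 to 10.5. In cluster 2, 4 of 4 regions on chromosome 10 between 84148464 and 84174362 were higher (2.03 to 3.10), as were 4 of 9 on chromosome 7 between 86642573 and 86677154 (2.71 to 5.33). In cluster 1, 4 of 6 regions on chromosome 11 between 84382922 and 84399662 were higher (2.26 to 2.73), as were 4 of 21 on chromosome 8 between 19920317 and 19977822 (2.18 to 2.64). These windows were picked after their values were seen. Their genes are not named here, and they are the places to look first with an annotation on mm9.

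The cells' shares of single chromosomes varied far more than sampling gives, and regions over 50 Mb apart on 1 chromosome still opened together. The median variance ratio of open regions was 6.11 where simulated data reached 1.03, which argues against sampling. Within clusters 1, 2 and 3 the median ratio was 5.91, 7.52 and 4.75, with a mean of 6.04 when weighted by cells. All of these lay above the 3.56 that keeping 0.5 of the excess over 1 would give, so differences between the 3 clusters do not account for most of it. Pairs over 50 Mb apart correlated at 0.486 of the level of pairs 1 to 5 Mb apart, as a mean of the ratios of single chromosomes. This was under the 0.8 set for a flat effect, and it argues against gain or loss of whole chromosomes as the only source of these correlations. The test cannot say how much of the spread in chromosome shares such changes give. Regions near each other also open together, which lowers the ratio whether or not chromosome number differs. What remains at long distance may still hold changes in chromosome number, unequal release of nuclear material on the chip or real differences between chromosomes.

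The 3 clusters of cells may reflect differences other than chromatin state, and 3 such explanations were tested. After thinning, the index between odd and even autosomes was 0.758, and membership of the cells kept matched that of the 3 clusters at 0.822. This argues against the number of open regions per cell as their whole cause. The simulated data, at most 0.00805, were drawn at equal depth. They therefore cannot show an effect of depth that thinning leaves behind, and the 32 shallowest cells were left out. Regions more often open than in a pair of cells of the other 2 clusters made up 9.92% in cluster 2 and 6.86% in cluster 3, above the 6.76% and 4.73% that were the highest of 100 sets of simulated doublets, which argues against doublets as the whole of either. In cluster 1 they made up 1.27%, within the simulated values of up to 4.89%, so this test cannot decide there. A doublet holds the open regions of 2 cells, yet the median of cluster 1 was the lowest, 3628 open regions against 4778 and 3700 in clusters 2 and 3. This argues against doublets of their cells as the whole of cluster 1, while doublets as a part of it stay open. Runs of neighbouring title numbers stay open for the division between clusters 1 and 2, because the index of at least 0.632 between odd and even autosomes within each set of numbers does not show that the same groups were found, and within the highest numbers membership matched at 0.292, below all 100 random sets of cells. Cluster 3 was found within every set, with an overlap of at least 0.778 against a limit of 0.5. This argues against runs that fill whole sets of numbers as its cause. Runs shorter than a set, or crossing the boundary between sets, stay open for cluster 3. The test cannot decide on them, because a set then holds cells from inside and outside the run. The share of cluster 3 differed between and within sets, and the labels do not say whether the numbers follow chips or days.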
